A study of Mus musculus with 36 samples.

How the data were processed

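Poly(A) RNA sequencing of mouse embryos (strain B6D2F1) was deposited as 36 libraries in 12 groups of 3. The groups crossed fertilization (in vitro fertilization, IVF, or natural mating, NM) with 2-cell embryos (E1.5), morulae (E2.5), inner cell mass (ICM) and trophectoderm (TE) of E3.5 blastocysts, and epiblast (Epi) and extraembryonic ectoderm (ExE) of E7.5 embryos. Per the labels, embryos were dissociated with enzymes and the cells lysed and reverse transcribed with an oligo(dT) primer. Nothing in the labels says how many cells or embryos went into a library, or whether the replicates of a group came from separate embryos or pools, so each p measures the spread between these samples and not between litters or fertilization days.

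The deposited count table holds counts of reads for 24391 genes, with no normalization. Per the file headers, the table follows the layout of featureCounts, and its Length column is of another unit, bases of exon. The labels name HISAT2 2.1.0, featureCounts 1.6.1, CASAVA, edgeR and the genome build mm9. The strand setting, the handling of read pairs and the filters are not given in the sources used here. Most counts above 100 were even numbers, so both mates of a pair appear to have been counted, and 2 counts can stand for 1 fragment. The second table of the authors gives log2 values for 22966 genes. These values equal the log2 of CPM plus 1, computed from the column totals, to within 5e-06. The count table was used for every test here, and the log2 table was used for that check alone. Histone modification data named by the title of the series were not used here.

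Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. DESeq2 1.42.0 served as an alternative, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for depth, GC content and plots. Each comparison of 2 groups was fitted on its own 6 libraries with TMM scaling, the filterByExpr filter, glmQLFit and glmQLFTest, 2-sided, and Benjamini-Hochberg adjustment over the genes tested. A gene is called higher or lower at an adjusted p under 0.05, with no fold minimum. The fitted log2 fold changes carry a prior count of 0.125, and each SE was taken from the F statistic. The comparisons were IVF against NM in each of the 6 stages and tissues, TE against ICM and ExE against Epi in NM libraries (and, outside those fixed beforehand, in IVF libraries), and the difference of the IVF effect between TE and ICM and between ExE and Epi. A fit over all 36 libraries with stage or tissue as a factor completed them. CPM (counts per 1000000 counts of a library) printed beside a fold change are TMM-scaled means with the SD over 3 libraries.

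Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, where at least 5 members passed the filter. Camera with an estimated correlation and fry were run beside it. The lists covered trophectoderm, inner cell mass and naive pluripotency, primitive endoderm, post-implantation epiblast, primitive streak and mesoderm, extraembryonic ectoderm and trophoblast stem cells, and ectoplacental cone and later placenta. Other lists covered visceral endoderm, maternal decidua and stroma, blood and immune cells, cumulus cells, 2-cell embryo activation, oocyte maternal genes, maternally and paternally expressed imprinted genes, histone methylation enzymes and the DNA methylation machinery. The last covered p53 targets, amino acid and unfolded protein stress, oxidative stress, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis and uptake, heat shock, immediate early genes, and the S and G2/M phases of the cell cycle. A separate measure took the genes that were higher in NM Epi than in NM ExE, or lower, at an adjusted p under 0.01 and a log2 fold change of at least 2, and gave their median change with IVF in ExE. Its value without an IVF effect came from 100 simulated draws.

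The comparisons, tests, lists, first alternatives and the rule for naming genes were written before the data were examined. By that rule, the 8 genes higher and the 8 lower with the smallest adjusted p were named for each stage or tissue. They needed a log2 fold change of at least 1 in size, a mean log2 CPM of at least 2, no overlap between the groups, and a symbol that is not a clone or model name. For the lineage contrasts, the interactions and the fit over all stages, 5 were taken in each direction. Members of a described list with a known function were named whether called or not.

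Those alternatives were DESeq2, RLE and upper-quartile factors, no filter on low counts, a filter of 5 CPM in 3 libraries, a fold minimum of 2, the replicate number as a block, the fit of all 36 libraries, and leaving out each library in turn. Halving the counts, removing each library's trend on exonic length and GC content (splines with 5 degrees of freedom each), and leaving out ribosomal protein genes with Rn45s were chosen after seeing the data. The tests of X-linked and Y-linked genes and of development in the closing section were also added after seeing the data.

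The procedure was tested on simulated counts with the measured means, library sizes and dispersions, in which 200 genes were changed by 2-fold or 4-fold. Of the 4-fold changes, 65% were recovered in 2-cell, 66% in morula, 68% in ICM, 91% in TE, 40% in Epi and 29% in ExE. Of the 2-fold changes, these shares were 13%, 38%, 13%, 52%, 4% and 0%. At most 10 unchanged genes were called in a comparison. A list of 25 genes raised together was called, and 0 of 25 unchanged lists were. The simulated genes varied independently, so this does not test how correlation between the genes of a list affects the calls.

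Library totals in units of 1000000 counts ran from 8.29 to 28.7. Variation between replicates exceeded counting error in each group, with a chi-square per degree of freedom between 8.3 and 160.49. Where a group had 0 counts, a floor of 3 counts over the 3 libraries of the group gave the lower bound of a fold. With 1 to 3 counts, the ratio is given with a 95% counting interval. Floors and intervals cover counting error only.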

Results

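Gene expression was measured by poly(A) RNA sequencing in mouse embryos that were fertilised and cultured in vitro (IVF) and in embryos from natural mating that developed in the mother (NM). The series title names extra-embryonic tissue, implantation and placenta of IVF embryos as its subject. Libraries were made at the 2-cell stage (E1.5), the morula (E2.5), from inner cell mass (ICM) and trophectoderm (TE) of the blastocyst (E3.5), and from epiblast (Epi) and extraembryonic ectoderm (ExE) at E7.5, with 3 libraries for each of the 12 groups. How IVF embryos were brought to E7.5 is not given in the sources used here. Mean library totals in units of 1000000 counts (± SD, n = 3) were 18.3 ± 1.54 in NM and 15.9 ± 2.36 in IVF at the 2-cell stage, and 9.43 ± 1.52 and 10.8 ± 1.02 in morulae. They were 20.5 ± 4.45 and 14.7 ± 1.72 in ICM, 19.07 ± 1.52 and 11.4 ± 1.72 in TE, 16.5 ± 3.54 and 27.5 ± 1.50 in Epi, and 15.3 ± 4.397 and 13.2 ± 2.57 in ExE.

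Library composition differed between NM and IVF libraries. Ribosomal protein genes took 32.5% ± 1.67 of counts in NM Epi and 11.9% ± 0.381 in IVF Epi, and 22.4% ± 3.00 in NM ExE and 15.4% ± 0.584 in IVF ExE. Among counts above 100, 89.7% ± 0.504 were even in NM Epi and 68.5% ± 1.88 in IVF Epi, against 90.6% ± 2.01 and 80.3% ± 3.24 in ExE. The ribosomal RNA precursor Rn45s took 1.70% ± 0.591 of counts in NM ICM and 0.277% ± 0.0195 in IVF ICM, and 1.24% ± 0.168 and 0.230% ± 0.0283 in TE, with no overlap. Smaller differences without overlap were found earlier: Rn45s took 0.684% ± 0.0895 in NM and 0.495% ± 0.00637 in IVF morulae, and 0.246% ± 0.0405 and 0.192% ± 0.00484 at the 2-cell stage. The share of even counts was 70.4% ± 0.445 in NM and 74.0% ± 0.399 in IVF morulae. A mean of 11570.7 genes had a count in NM Epi and 15207.7 in IVF Epi. Single libraries also stood out by the number of genes with a count: TE of NM replicate 2 had 20290, 2-cell NM replicate 3 had 19333, and 2-cell IVF replicate 1 had 17373. In ICM of NM replicate 1, ribosomal protein genes took 18.1% of counts, the highest share in that tissue.

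**Figure D1:**
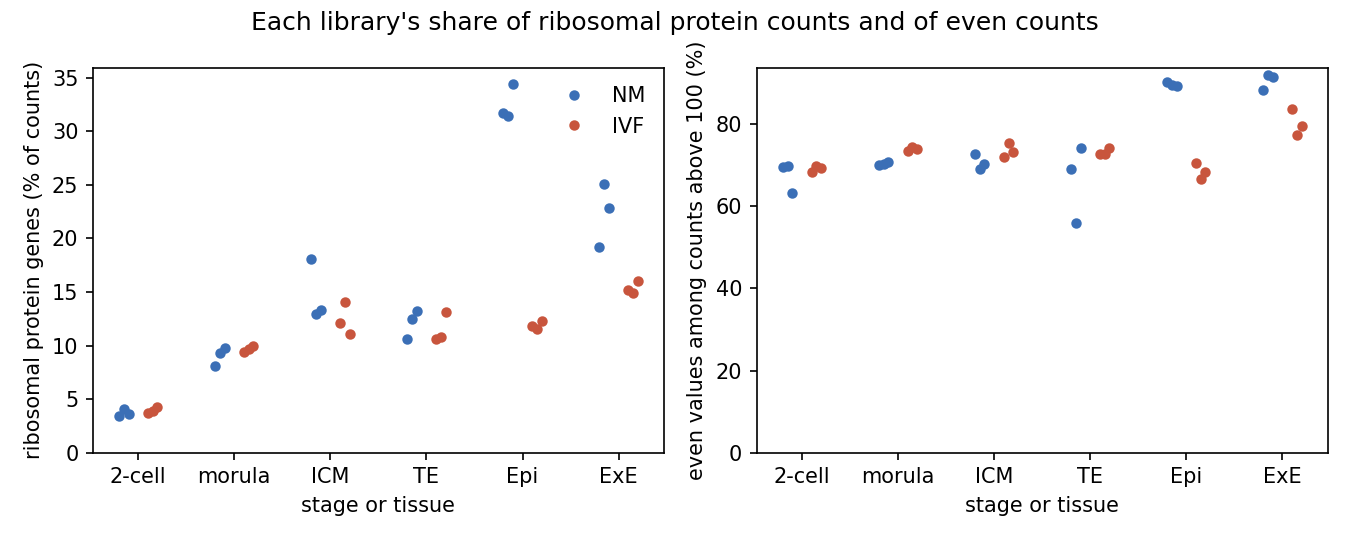
Each point is 1 library, NM in blue and IVF in red, by stage or tissue. The left panel gives the percent of counts in ribosomal protein genes and the right panel the percent of even values among counts above 100, and the NM libraries of Epi and ExE lie above the IVF libraries in both.

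The lineage markers of the NM blastocyst followed the tissue labels. Gata3, a transcription factor of trophoblast, was higher in TE than in ICM by 3.81 ± 0.20 (log2 fold change ± SE, adjusted p = 6.5e-05, edgeR), with 382.6 ± 36.03 CPM in TE and 27.2 ± 2.12 in ICM. Dab2, an endocytic adaptor of epithelia, was higher by 4.33, the ephrin ligand Efnb2 by 3.76, moesin (Msn) by 3.43 and the splicing regulator Mbnl3 by 4.52. On the ICM side, Klf2, a naive pluripotency factor, fell by 2.60 in TE, and Gsc, the aquaporin Aqp8, Syt9 and Nkx6-2 had log2 fold changes of -4.69, -3.85, -3.14 and -3.16. Of 24 trophectoderm genes tested, 19 rose and 0 fell in TE (median 2.81, camera adjusted p = 1.5e-29, and 0.0922 with an estimated correlation). Of 25 ICM and naive pluripotency genes, 0 rose and 17 fell (median -1.97, adjusted p = 0.0947 with an estimated correlation). In all, 1381 genes were higher and 1054 lower of 12145 tested.

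The E7.5 tissues of NM embryos also carried their own markers. Elf5, which guards trophoblast stem cell identity, had 203.0 ± 49.5 CPM in ExE and 0.114 ± 0.197 in Epi, and the trophoblast ligand Wnt7b had 223.5 ± 51.4 and 0.114 ± 0.197. Both differed at an adjusted p of 2.9e-05 (edgeR). Cited1 (log2 fold change 3.16), the actin regulator Arpc1b (4.51) and Amn (3.44), a partner of cubilin in visceral endoderm, were higher in ExE. Epiblast and streak genes were lower: Pou5f1 by -7.66, brachyury (T) by -3.99, follistatin (Fst) by -5.00, Igfbp2 by -4.45 and Cd24a by -3.08. The lists moved with the labels and were called with an estimated correlation as well. Of 24 ExE and trophoblast stem cell genes 10 rose and 0 fell (adjusted p = 0.0318 with an estimated correlation), and of 27 post-implantation epiblast genes 0 rose and 9 fell (0.0171). Visceral endoderm genes were higher in ExE too, with 14 risen and 1 fallen (0.0318). In all, 270 genes were higher and 258 lower of 10313 tested.

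The same contrasts were run in IVF libraries, outside the comparisons fixed beforehand. TE against ICM had 346 genes higher and 289 lower of 11223, and ExE against Epi 1816 and 2084 of 12990. Whether NM and IVF differ in these contrasts is the question of the interaction tests.

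IVF against NM was compared at each stage, to ask what in vitro fertilization and culture changed. The numbers of genes higher and lower were 214 and 250 of 12735 tested at the 2-cell stage, 322 and 376 of 10337 in morulae, 448 and 682 of 11565 in ICM, 1155 and 1256 of 11594 in TE, 1188 and 1379 of 12620 in Epi, and 61 and 214 of 11027 in ExE. With a fold of 2 or more, these became 176 and 190, 149 and 189, 338 and 584, 463 and 744, 1035 and 1107, and 61 and 209. Counts of called genes are not a ranking of the stages, since the biological coefficient of variation ran from 0.345 in TE to 0.807 in ExE. Upper-quartile factors moved the median of all genes from 0.103 to 0.242 in Epi and from -0.0464 to 0.184 in ExE, and changes there are relative to those medians. One fit of all 36 libraries with a shared dispersion ended the calls of 10 of 22 named genes at the 2-cell stage, 12 of 31 in morulae, 13 of 35 in ICM, 27 of 51 in TE, 9 of 33 in Epi and 5 of 32 in ExE. Of 142 tests of gene lists, 37 were called, and 4 of these held with an estimated correlation: cholesterol and primitive endoderm genes in ICM, and p53 targets and immediate early genes in TE.

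The calls that ended in the fit of all 36 libraries were, at the 2-cell stage, those of Omt2a, Omt2b, Antxr1, Bfsp1, Lmo1, Rnf103, Foxa1, Oosp1, Cdc20 and Mcm6. In morulae they were those of Trim43c, Nabp1, Rragd, Phlda3, Rps27l, Hand1, Klf4, Klf5, Esrrb, Aqp3, Tead4 and Tet2, and in ICM those of Enpep, Xlr3a, Magea5, Fam25c, Sox17, Lama1, Fgf4, Phlda3, Egr1, Junb, Hmox1, Srxn1 and Kmt2a. TE lost those of Gata2, Tfap2a, Tfap2c, Krt7, Krt8, Lgals3, Tspan8, Nanog, Sox2, Pou5f1, Dppa4, Fbxo15, Tdgf1, Klf4, Tet2, Phlda3, Cdkn1a, Mdm2, Eda2r, Fos, Egr1, Junb, Hspb8, Hspb1, Trib3, Magea3 and Enpp1. Epi lost those of Otx2, T, Mesp1, Utf1, Fgf8, Hoxb1, Mixl1, Gsc and Zic3, and ExE those of Wnt7b, Eomes, Apoa1, Amn and Apom.

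**Figure D2:**
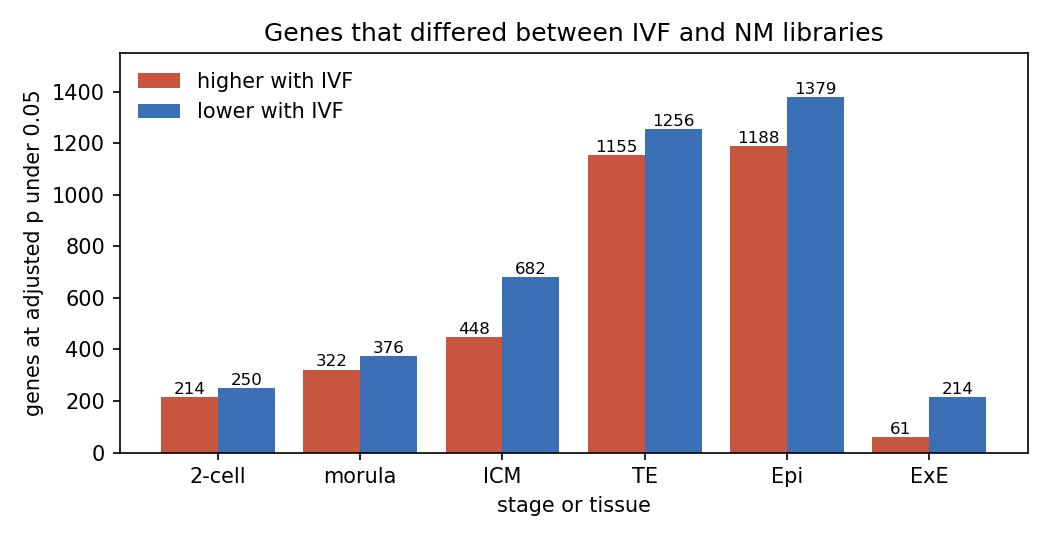
Bars give the number of genes higher (red) and lower (blue) with IVF at an adjusted p under 0.05 in each stage or tissue, from 3 IVF and 3 NM libraries each. TE and Epi had 2411 and 2567 such genes and ExE had 275.

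At the 2-cell stage, single genes of the oocyte rose with IVF and single genes of mitochondria and trafficking fell. The lists of oocyte maternal genes (2 risen and 0 fallen of 30, camera adjusted p = 0.201) and oxidative phosphorylation genes (1 and 1 of 40, 0.476) did not pass. Omt2a and Omt2b, genes expressed in maturing oocytes, were higher by 1.52 ± 0.16 and 1.43 ± 0.16 (adjusted p = 0.00156 for both, edgeR). They are near-identical, so reads may have been shared between them. Oosp1, which encodes an oocyte-secreted protein, rose by 1.18, the p53 target Gtse1 by 1.30, Rps27l by 0.76 and the antioxidant enzyme Prdx2 by 2.19. The lists of p53 targets and oxidative stress genes were not called at this stage, with median log2 fold changes of -0.00216 and -0.106. Cbln1, a secreted synapse organiser, rose from 11.7 ± 4.74 to 147 ± 19.4 CPM (log2 fold change 3.65, adjusted p = 0.00112). The mTOR complex partner Prr5 rose by 4.83, the collagen receptor Antxr1 by 2.12, the lens filament gene Bfsp1 by 2.15 and the transcription regulator Lmo1 by 2.02, and Cd1d1, a lipid antigen presenter, went from 0.0767 to 25.05 CPM. Lower were Ndufv2 of respiratory complex I (-1.58), the electron transfer flavoprotein Etfa (-1.68), the proton pump subunit Atp6v1c1 (-1.35), Trappc6b of the trafficking complex (-1.92) and the ubiquitin ligase Rnf103 (-2.54). The splicing factor Hnrnph1 (-1.24), the pioneer factor Foxa1 (-1.68) and Lrr1 (-1.32) were lower too.

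The S and G2/M cell cycle list was higher at the 2-cell stage (camera adjusted p = 0.0037, and 0.897 with an estimated correlation), a call that fry did not make. Of its 36 genes, 2 rose, the anaphase activator Cdc20 by 0.92 and the replication licensing factor Mcm6 by 0.69, and 0 fell. The counts of called genes at this stage changed with 1 library left out, while 0 named genes changed direction. Without IVF replicate 1, 2 or 3, 27 and 16, 27 and 6, and 66 and 29 genes were higher and lower. Without NM replicate 1, 2 or 3 there were 488 and 477, 174 and 120, and 112 and 81. Gtse1 and Oosp1 lost their call without IVF replicate 1 or 2, Rps27l, Cdc20 and Mcm6 without any IVF replicate or NM replicate 3, and Ndufv2, Etfa, Hnrnph1 and Atp6v1c1 without IVF replicate 2.

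In morulae, genes that prepare the trophectoderm were lower with IVF, together with pluripotency factors. Gata3 fell by 3.25 ± 0.36 (adjusted p = 8.0e-05, edgeR), the epithelial keratins Krt8 and Krt18 fell by 4.07 and 2.12, the water channel Aqp3 by 1.80, Hand1, a giant cell factor, by 1.21 and Eomes, a T-box factor of trophoblast stem cells, by 3.35. Tead4, which acts upstream of the trophectoderm programme, rose by 0.56. Of 20 trophectoderm genes tested, 1 rose and 7 fell (camera adjusted p = 4.3e-08, and 0.102 with an estimated correlation), and 1 rose and 10 fell adjusted over the list alone. Of 24 ICM and naive pluripotency genes 0 rose and 6 fell (2.0e-04, and 0.102 with an estimated correlation), among them Sox2 (-5.77), Klf4 (-0.80), Klf5 (-1.17), Esrrb (-1.32) and Tet2 (-2.64).

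Some p53 targets and the metal handling genes Mt1, Mt2 and Slc30a1 rose in IVF morulae. The p53 targets Ccng1, Phlda3 and Rps27l rose by 2.44, 2.86 and 0.68, and of 23 p53 targets 3 rose and 1 fell (adjusted p = 0.0109, and 0.187 with an estimated correlation). The lists of amino acid and unfolded protein stress (1 risen and 3 fallen of 23, adjusted p = 0.105), heat shock (1 and 3 of 19, 0.0583) and oxidative stress (3 and 1 of 26, 0.756) did not pass. The metal binding proteins Mt1 and Mt2 rose by 1.24 and 1.63, and the zinc exporter Slc30a1 rose from 6.34 ± 2.40 to 80.5 ± 2.89 CPM (3.66 ± 0.36, adjusted p = 2.8e-05). Trim43c, a preimplantation gene from a family of close copies, rose by 1.72, with Rps2 (1.19), Larp1b (1.28), the DNA repair genes Nabp1 (1.34) and Mad2l2 (1.35). Actins fell, with log2 fold changes of -2.04 ± 0.13 for Actb (adjusted p = 4.9e-07) and -1.29 for Actg1. So did the chaperone Hsp90aa1 (-1.28), the helicase Eif4a2 (-1.40), the amino acid sensor Rragd (-1.94), the ADP carrier Slc25a5 (-1.38), the proton pump partner Atp6ap2 (-1.28) and the paraspeckle RNA Neat1 (-4.93). Calls ended for Eomes and Tead4 without NM replicate 1 or 2, for Sox2 without NM replicate 1, for Krt18 and Aqp3 without NM replicate 3, and for Tead4 without IVF replicate 2 or 3. The counts of higher and lower genes both moved past 1.5 times without NM replicate 2 (166 and 155), NM replicate 3 (202 and 226) or IVF replicate 1 (193 and 248). Without NM replicate 1 (227 and 215) the count of lower genes alone did.

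In ICM, primitive endoderm genes were lower with IVF and cholesterol synthesis genes were higher. Sparc, a matrix glycoprotein of the endoderm, fell by 3.32 ± 0.27 (adjusted p = 3.7e-04, edgeR), from 372.2 ± 80.4 to 37.2 ± 8.89 CPM. The laminin chains Lamc1 and Lama1 fell by 1.85 and 3.41, the collagen chaperone Serpinh1 by 3.88 and the endoderm factor Sox17 by 1.16. Of 17 primitive endoderm genes, 0 rose and 7 fell (camera adjusted p = 5.6e-08, and 0.0388 with an estimated correlation), and 1 rose and 12 fell adjusted over the list alone. Among cholesterol genes, Cyp51 rose by 2.65, Fdps by 2.02 and Msmo1 by 2.04, and of 24 tested 14 rose and 0 fell (8.6e-13, and 0.0388 with an estimated correlation).

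Several pluripotency regulators fell in ICM. Klf5 fell by 5.36 ± 0.29 (adjusted p = 8.1e-05), Klf4 by 2.12, the growth factor Fgf4 by 2.05 and the Nodal co-receptor Tdgf1 by 2.05, while Nanog did not pass (0.23, adjusted p = 0.675). Of 25 genes of the ICM list, 0 rose and 7 fell (5.6e-08, and 0.0934 with an estimated correlation). The hydroxylase Tet1 fell by 1.83 and the histone methyltransferase Kmt2a by 2.23, with 6 of 31 histone methylation enzymes and 4 of 18 DNA methylation genes fallen and 0 and 1 risen (0.00765 for both, and 0.118 and 0.1203 with an estimated correlation). The acetyltransferase Crebbp fell by 5.08 and the repressor Rest by 6.14. Klf9 (-3.08), the lipid droplet protein Plin3 (-3.21), Fam25c (-3.62) and Cmip (-3.24) were lower as well.

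Stress genes and immediate early genes differed in direction in ICM. Phlda3 and Ccng1 rose by 2.25 and 1.66, while Mdm2 (0.91, adjusted p = 0.132) did not pass, except with no low-count filter (0.0357), and of 24 p53 targets 6 rose and 1 fell (3.8e-05, and 0.172 with an estimated correlation). Hmox1, which breaks down heme, rose by 2.38 and the peroxiredoxin repair enzyme Srxn1 by 2.22, with 6 risen and 1 fallen of 28 oxidative stress genes (1.8e-04, and 0.198 with an estimated correlation). The immediate early genes Egr1 and Junb fell by 2.56 and 1.81, with 0 risen and 9 fallen of 20 (2.7e-06, and 0.0934 with an estimated correlation). That list was set beforehand as a sign of cell dissociation, and a difference in dissociation or handling was not separated from its fall. The glutathione enzyme Gsto1 (2.18), the peptidase Enpep (2.57), the phosphatase Alppl2 (3.09), Gpd1l (2.00), Xlr3a (2.69), Magea5 (2.86) and Trim43b (2.77) were higher, the last 3 from families of near-identical copies. Smaller lists moved too: post-implantation epiblast (0 risen and 4 fallen of 20, adjusted p = 0.0162), primitive streak (0 and 2 of 11, 0.01) and 2-cell activation (1 and 0 of 6, 0.0147), with 0.198, 0.128 and 0.141 with an estimated correlation. The streak, 2-cell activation and histone methylation lists lost their call with the length and GC trend removed. Sox17 lost its call without NM replicate 2 or 3 or any IVF replicate, Egr1 without NM replicate 2 or 3 or IVF replicate 1 or 2, and Hmox1 without NM replicate 2 or IVF replicate 1. Without NM replicate 1, 743 and 805 genes were higher and lower and Nanog changed by -0.02, while the counts fell to 161 and 280, 175 and 294, 197 and 361, 241 and 425, and 243 and 399 without NM replicates 2 and 3 and IVF replicates 1, 2 and 3.

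In TE, transcription factors of the trophoblast lineage were lower with IVF. Gata3 fell by 3.84 ± 0.18 (adjusted p = 7.1e-09, edgeR), from 361.2 ± 32.2 to 25.2 ± 4.98 CPM, Elf5 by 3.68 ± 0.42 (3.2e-05), Gata2 by 2.24 and Tfap2a by 1.02. The keratin Krt8 fell by 0.77, the lectin Lgals3 by 2.63 and the tetraspanin Tspan8 by 1.71. Cdx2, which sets up the lineage, did not pass (-0.23, adjusted p = 0.469), and Hand1, Krt7 and Tfap2c rose by 4.04, 1.85 and 0.54. Of 24 trophectoderm genes, 3 rose and 12 fell (camera adjusted p = 6.4e-09, and 0.233 with an estimated correlation), and 3 rose and 14 fell adjusted over the list alone. Of 23 ExE and trophoblast stem cell genes, 3 rose and 10 fell (1.8e-05, and 0.0922 with an estimated correlation).

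Genes of the ICM did not move together in TE. The pluripotency factors Nanog, Sox2 and Pou5f1 rose by 1.66, 2.38 and 0.91 (adjusted p = 6.5e-06, 2.1e-05 and 0.0059), with Dppa4 (0.96) and Fbxo15 (0.43), while Klf5, Tdgf1, Klf4 and Tet2 fell by 5.30, 1.16, 0.63 and 1.15. In the fit of all 36 libraries the calls of Nanog, Sox2 and Pou5f1 ended (adjusted p = 0.294, 0.107 and 0.475). With 5 risen and 4 fallen of 24, the list did not pass (adjusted p = 0.662). Some ICM cells in the IVF TE libraries were not excluded as a source of the rises. Other genes that fell were the actin crosslinker Actn4 (-3.78 ± 0.15, adjusted p = 2.1e-09), the growth factor Pdgfa (-4.38), the G protein Gnai2 (-2.86), the pyrophosphatase Enpp1 (-5.15) and Plin3 (-2.60). Rn45s, the ribosomal RNA precursor, went from 12209 ± 1796 to 2343 ± 274 CPM (-2.38 ± 0.12).

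Cholesterol synthesis genes and p53 targets rose in TE. Cyp51, Fdps, Msmo1 and Sqle rose by 2.53, 1.99, 2.11 and 1.37, and of 24 cholesterol genes 19 rose and 1 fell (adjusted p = 1.6e-16, and 0.0922 with an estimated correlation), or 21 and 1 adjusted over the list alone. Acly, which supplies acetyl-CoA, rose by 1.62. The p53 targets Ccng1, Phlda3, Eda2r, Cdkn1a and Mdm2 rose by 2.15, 2.38, 2.87, 1.22 and 0.67, with 16 risen and 1 fallen of 24 (5.7e-09, and 0.0481 with an estimated correlation). The immediate early genes Fos, Junb and Egr1 fell by 2.90, 2.73 and 1.97, with 0 risen and 10 fallen of 19 (3.7e-07, and 0.0481 with an estimated correlation). Dissociation or handling of the embryos was not separated from this fall either. The small chaperones Hspb8 and Hspb1 rose by 4.29 and 2.87, the pseudokinase Trib3 by 2.56 and the endoplasmic reticulum factor Manf by 1.80, while Asns (0.50) and Ddit3 (0.43) did not pass. Other genes that rose were Magea3 (6.84), Tceal8 (4.72), the piRNA factor Mael (4.07) and Pramel5 (1.82), with Bhmt (2.14) and Pmm1 (2.14). Magea3 and Pramel5 have near-identical copies.

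Other lists called in TE were amino acid and unfolded protein stress (9 risen and 0 fallen of 25, adjusted p = 2.6e-04), oxidative stress (13 and 4 of 28, 0.00116), oxidative phosphorylation (0 and 12 of 40, 0.00111), glycolysis and hypoxia (1 and 7 of 29, 0.0235), heat shock (5 and 5 of 19, 0.0291), visceral endoderm (2 and 0 of 10, 0.0479) and 2-cell activation (3 and 0 of 8, 0.0479). With an estimated correlation these gave adjusted p values of 0.0958, 0.233, 0.692, 0.233, 0.233, 0.316 and 0.317. Tfap2c lost its call without any single library, Krt7 without any but IVF replicate 1, Tdgf1 without any but NM replicate 3, Fbxo15 without any but NM replicate 1, Klf4 without NM replicate 1 or any IVF replicate, and Trib3 without NM replicate 2 or 3 or IVF replicate 2 or 3. Calls also ended for Cdkn1a without NM replicate 2 or IVF replicate 3, for Mdm2 without NM replicate 3 and for Hand1 without IVF replicate 2. Calls also ended for Tfap2c and Fbxo15 with no low-count filter, for Krt7, Trib3 and the visceral endoderm list with the replicate block, for that list with RLE factors, and for oxidative phosphorylation with fry. Removing the length and GC trend ended those of Klf4 (-0.59, about as large as before), Fbxo15 (0.22) and the visceral endoderm, 2-cell activation and heat shock lists. The counts moved past 1.5 times without NM replicate 2 (750 and 821) and IVF replicate 2 (702 and 832).

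**Figure D3:**
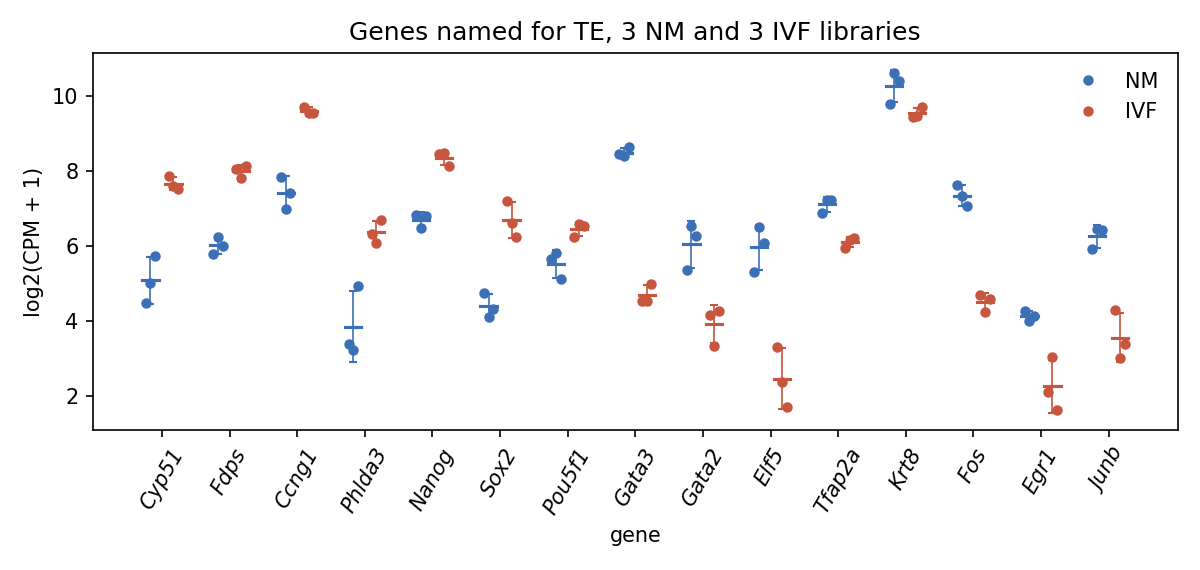
Points give log2(CPM + 1) of 15 genes in the 3 NM (blue) and 3 IVF (red) TE libraries, with horizontal lines at the mean and error bars of 1 SD. Cholesterol genes, p53 targets and Nanog, Sox2 and Pou5f1 lie higher with IVF, and Gata3, Gata2, Elf5, Tfap2a, Krt8, Fos, Egr1 and Junb lie lower.

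In Epi, ribosomal protein and respiratory chain transcripts were lower with IVF. Rps14 fell from 28465 ± 316 to 2014 ± 257 CPM (-3.82 ± 0.11, adjusted p = 3.5e-06, edgeR), with Rplp1 (-3.74), Rps12 (-3.28), Rps26 (-3.01), Rps19 (-3.004), Rps17 (-2.78), Rpl12 (-2.72) and Rpl23a (-2.57), and 84 of 90 ribosomal protein genes fell. Cox7c, Ndufa4, Ndufa1 and Cox6c of the respiratory chain fell (-2.65, -2.04, -2.37 and -2.44), and of 40 oxidative phosphorylation genes 0 rose and 28 fell (camera adjusted p = 2.3e-26, and 0.243 with an estimated correlation). The antioxidant enzymes Gpx4 and Sod1 fell by 2.69 and 1.89, with 1 risen and 13 fallen of 29 oxidative stress genes (7.5e-08, and 0.342 with an estimated correlation).

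Patterning genes of the gastrula moved both ways in Epi. The list of primitive streak and mesoderm genes did not pass, with 3 risen and 5 fallen of 25 (adjusted p = 0.872, camera direction down, median 0.145), nor did post-implantation epiblast genes (3 and 5 of 29, 0.540). The streak genes T, Mesp1, Mixl1, Fgf8 and Gsc fell by 0.96, 1.75, 1.75, 2.57 and 3.67, and Pou5f1, L1td1 and Utf1 of the epiblast fell by 1.45, 1.38 and 2.00. Otx2, an anterior epiblast factor, rose by 2.05 ± 0.18 (adjusted p = 1.9e-04), with Zic3 (1.58), Hoxb1 (1.62) and Bmp4 (3.04). Long transcripts were among those that rose: Prtg (3.35), Kif5b (2.06), Mbtd1 (1.99), Ncor1 (2.16), Impad1 (2.54), Ttc3 (1.66) and the nuclear RNA Malat1 (4.74). Gata3, which marks trophoblast at this age, had 0 counts in NM Epi and was at least 96.8-fold higher in IVF Epi. That bound is lower if 2 counts stand for 1 fragment.

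The log2 fold changes in Epi rose with exonic length (Spearman 0.445 across genes, which are not independent replicates), with medians of -0.905 and 0.834 in the 20% shortest and the 20% longest genes. With the length and GC trend removed, 971 genes were higher and 597 lower, Ttc3, Cox7c, Ndufa4, Ndufa1, Cox6c, Sod1, T, Pou5f1, Fgf8 and Gsc and the oxidative phosphorylation list lost their call, with values of -0.14 for Ndufa4, -0.09 for Sod1, -0.18 for Pou5f1, -0.63 for T and -1.39 for Gsc, and Mesp1 (0.41) and Utf1 (0.05) changed sign. Without IVF replicate 1, 2 or 3 there were 724 and 947, 170 and 768, and 211 and 825 genes higher and lower. Calls ended for Pou5f1, Hoxb1, Bmp4, Gsc and Zic3 without IVF replicate 1, and also Mesp1, Fgf8 and Mixl1 without IVF replicate 2, or Fgf8 and Mixl1 without IVF replicate 3. They ended for Hoxb1, Bmp4, Gsc and Zic3 without NM replicate 2, for Bmp4 and Mixl1 without NM replicate 1, for Mixl1 without NM replicate 3, and for Bmp4 with the replicate block.

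In ExE, embryonic globins and a few stromal genes were higher with IVF, and Wnt7b, Eomes and some visceral endoderm genes were lower. The embryonic globins Hbb-bh1 and Hba-x went from 1.05 ± 1.34 to 875.6 ± 234.7 CPM (9.85 ± 0.94, adjusted p = 0.0031, edgeR) and from 0.246 ± 0.307 to 189.2 ± 64.4 CPM (9.75 ± 0.84, 0.00184). Gypa, a red cell membrane protein, had 0 counts in NM ExE and was at least 160-fold higher. Of 7 blood and immune genes, 3 rose and 0 fell (camera adjusted p = 2.6e-12, and 0.111 with an estimated correlation), or 5 and 0 adjusted over the list alone, with a median of 9.72, or 6.55 with genes at 0 set to their bound. The smooth muscle actin Acta2 and the collagen Col1a2, also at 0 in NM, were at least 396-fold and at least 305-fold higher. These bounds, that of Gypa and the median of 6.55 would be lower if 2 counts stand for 1 fragment. Of 12 decidua and stroma genes 2 rose and 0 fell (median 3.74, adjusted p = 5.0e-06, and 0.111 with an estimated correlation).

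Wnt7b fell in ExE by 2.07 ± 0.29 (adjusted p = 0.0138) and Eomes by 1.69 ± 0.34 (0.0319), while Elf5 (-1.01, adjusted p = 0.0707) and Cdx2 (-1.65, 0.0966) did not pass. DESeq2 called both lower (0.00869 and 0.00898), and the fit of all 36 libraries called Cdx2 (0.0493). Of 26 ExE and trophoblast stem cell genes, 0 rose and 2 fell (6.5e-04, and 0.386 with an estimated correlation). The apolipoproteins Apoa1 and Apom and the endocytic receptor partner Amn fell by 1.16, 1.02 and 1.66, with 0 risen and 3 fallen of 22 visceral endoderm genes (3.7e-04, and 0.330 with an estimated correlation). Slc38a4, an imprinted amino acid transporter of the placenta, rose by 2.30 ± 0.28 (0.00836). The imprinted antisense RNA Kcnq1ot1 had 2 counts in NM, which can be 1 fragment, and a ratio of 493 (interval 136 to 4070, too narrow in that case). Of 24 paternally expressed imprinted genes 2 rose and 0 fell (0.0114, and 0.322 with an estimated correlation). Pou5f1, the epiblast factor, had 3.14 ± 1.46 (adjusted p = 0.292) and was higher in 3 of 3 IVF libraries, an order that chance gives to 10% of genes when both directions count. The fit of all 36 libraries called it (3.07, 1.6e-04).

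Other genes called in ExE had mixed functions, and the S and G2/M cell cycle list did not pass (0 risen and 0 fallen of 36, adjusted p = 0.524). The cyclin Ccnd2 rose by 4.24, Baiap2l1, which bends membranes, by 4.47, and Marcks by 2.05. The Y-linked helicase Ddx3y went from 0.572 to 104.5 CPM, and Eif2s3y (2.41 and 49.3 CPM, adjusted p = 0.108), Uty (0.604 and 11.6, 0.220) and Kdm5d (0.0402 and 3.17, 0.136), also Y-linked, were higher in each IVF than in each NM library. Male cells alone carry these genes, so the change of Ddx3y was not separated from the sex of the embryos. The other IVF against NM changes in ExE, and the difference of the effects between ExE and Epi, were not separated from sex either. Xist, which female cells express, had 12.5 CPM (0 to 26) in NM and 21.8 (6.14 to 48.6) in IVF ExE, and did not move the other way. Lower were the ferritin chain Ftl1 (-2.02), the mitochondrial tRNA ligase Lars2 (-2.17), the actin-binding Cotl1 (-1.93), the ubiquitin conjugase Ube2s (-1.78), Mrps24 (-2.29), Galk1 (-1.90), the lipid carrier Stard10 (-2.68) and the syndecan Sdc4 (-2.13). Oxidative stress (0 risen and 6 fallen of 27), oxidative phosphorylation (0 and 1 of 40) and post-implantation epiblast genes (0 and 0 of 22) were lower at adjusted p values of 1.9e-06, 3.8e-04 and 0.0379, and of 0.322, 0.458 and 0.322 with an estimated correlation.

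The ExE calls needed all 3 IVF libraries. Without IVF replicate 1, 2 or 3, 2 and 1, 2 and 1, and 2 and 2 genes were higher and lower. Of the called genes named here Hbb-bh1 and Hba-x alone kept their call, but 0 changed direction. Ftl1, for one, had log2 fold changes of -1.96, -2.01 and -2.04 in these fits. Without NM replicate 1, 205 and 485 genes were higher and lower. Kcnq1ot1 lost its call without NM replicate 2 or 3 and Apom without NM replicate 2. Upper-quartile factors gave 100 higher and 129 lower, a share higher of 43.7% in place of 22.2%, and ended the calls of Eomes and Apom, and the replicate block ended those of Gypa and Apom. With the length and GC trend removed, 9 genes were higher and 20 lower, and Marcks, Ccnd2, Ftl1, Cotl1, Mrps24, Galk1, Stard10, Wnt7b, Eomes, Apoa1, Apom, Amn, Col1a2, Gypa and Kcnq1ot1 lost their call. Of these, Apom (-0.06), Apoa1 (-0.11) and Amn (-0.50) lost most of their change, Ftl1 (-0.86), Galk1 (-0.73) and Cotl1 (-1.02) were nearer 0, and Eomes (-1.55), Wnt7b (-1.66), Marcks (1.62) and Ccnd2 (3.76) moved less. The fitted values of Gypa (10.30) and Col1a2 (11.23), which are not bounds, stayed about as large, and that of Kcnq1ot1 went from 8.56 to 6.92. Calls also ended for the lists of post-implantation epiblast, paternally expressed imprinted, oxidative stress and oxidative phosphorylation genes. With fry the ExE and trophoblast stem cell and oxidative phosphorylation lists lost theirs.

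**Figure D4:**
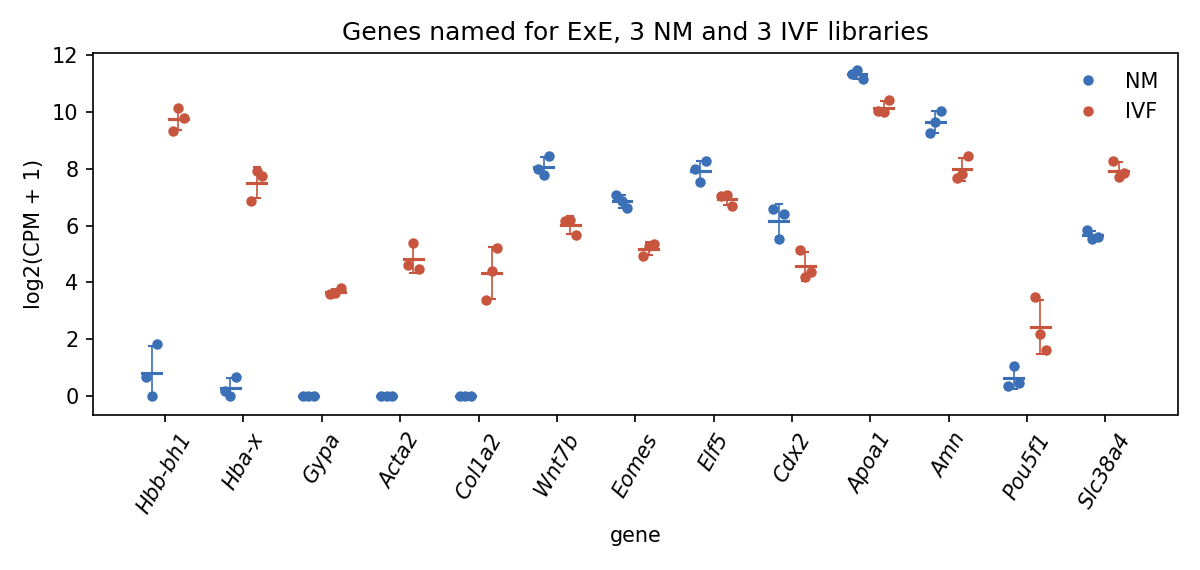
Points give log2(CPM + 1) of 13 genes in the 3 NM (blue) and 3 IVF (red) ExE libraries, with lines at the mean and error bars of 1 SD. Hbb-bh1, Hba-x, Gypa, Acta2 and Col1a2 are at or near 0 in NM, and Elf5, Cdx2 and Pou5f1 did not pass the test.

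The title of the series concerns ectopic histone marks outside the embryo proper, so genes of one E7.5 lineage were followed in the other. The 37 genes high in NM Epi had a median change of 0.91 with IVF in ExE, with 27 above 0 and 4 called higher, where simulation without an IVF effect gave 0.27 (0.10 to 0.42 over 100 draws). The 89 genes high in NM ExE had a median of -0.99, with 4 above 0 and 31 called lower, against -0.33 (-0.45 to -0.23). Without IVF replicate 1, 2 or 3, 0 of the first and 1 of the second genes were called in that direction, and without NM replicate 1 or 2, 8 and 2 of the first were called higher. The list of 22 post-implantation epiblast genes, fixed beforehand, had a median of -1.06 in ExE with 0 called genes (camera adjusted p = 0.0379, 0.322 with an estimated correlation, and 0.0803 with the length and GC trend removed). With the length and GC trend removed and the lists unchanged, the medians were 1.2 and -0.75 with 0 and 4 genes called in those directions, and the simulation did not include that trend. It also gave each gene 1 dispersion for all groups. Replicates of NM ExE varied more than those of IVF ExE, with a chi-square per degree of freedom of 111.55 to 160.49 against 20.478 to 25.301. The simulated medians may therefore be too small in size. The first median was 0.10 for a list with a log2 fold change of at least 1, where 5 of 73 genes were called higher and 10 lower and no simulation was run, 1.63 for one of at least 4, and 1.40 without NM replicate 3. Globin and stromal genes also rose in the same IVF ExE libraries. A difference in the cells collected was not separated from either median, and histone marks were not examined here.

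The difference of the IVF effects was tested itself. Between TE and ICM, 39 genes had a higher and 112 a lower effect in TE of 12733 tested. The transcription factor Gsc rose in TE and fell in ICM (1.82 and -1.60), and the RNA-binding protein Igf2bp1, the corepressor Sap30, asparagine synthetase Asns and the channel subunit Cacnb1 had effects of 0.53, 0.31, 0.47 and 1.17 in TE against -1.18, -1.65, -1.63 and -2.96 in ICM. Enpep and the p53 target Perp went the other way (-0.56 and -0.97 in TE, 2.59 and 1.44 in ICM), as did the pyrophosphate transporter Ank (-0.82 and 2.01). Enpp1 (-5.17 and -0.19) and Fos (-2.92 and 0.16) fell in TE alone. Cacnb1 lost its call without ICM of NM replicate 2.

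Between ExE and Epi, 164 genes had a higher and 57 a lower effect in ExE of 13248 tested. Rps26, Rpl23a and Rpl10 had effects of -0.69, -0.72 and -0.41 in ExE against -2.90, -2.45 and -1.66 in Epi, with Mrpl34 (-0.32 and -2.74) and Cox7b (-0.50 and -2.51). Neither this test nor that between TE and ICM was run with the length and GC trend removed. The log2 fold changes rose with exonic length in both E7.5 tissues, more so in Epi (Spearman 0.445, and 0.298 in ExE). That trend was therefore not separated from the difference between ExE and Epi. Igf2bp1 (-0.38 and 1.53) and Klhl22 (-1.23 and 3.19) rose in Epi and not in ExE. The early response gene Ier3 and the ubiquitin ligase Cbl had 0 counts in NM Epi and were at least 53.7-fold and at least 639-fold higher in IVF Epi. Both bounds are lower if 2 counts stand for 1 fragment. The transcription factor Elf1 had effects of -0.97 in ExE and 6.95 in Epi.

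Over all 6 stages and tissues, 145 genes were higher and 356 lower with IVF of 16212 tested. The germline genes Magea5, Magea2 and Magea8 were higher by 2.78 ± 0.40 (adjusted p = 1.2e-04), 4.35 and 3.26, the surface protein Cd24a by 1.49 and the chromatin remodeller Smarca2 by 1.57, each in the same direction in 6 of 6 stages. Histone genes Hist1h2ak and Hist1h2ag were lower by -4.51 ± 0.51 (1.5e-06) and -3.12, in 6 and 5 stages, and Rn45s, Palm and Rpl36 by -1.38, -1.31 and -1.29 in 6. Magea and histone genes have near-identical copies. The libraries were primed with oligo(dT) and their share of the ribosomal RNA precursor Rn45s differed between NM and IVF. A difference in library preparation was therefore not separated from the falls of Rn45s and the histone genes. Without ICM 63 and 218 genes were higher and lower, without TE 66 and 222, without Epi 130 and 194, without ExE 131 and 151, and without 2-cell 257 and 420. RLE factors gave 186 higher and 264 lower, the replicate block 28 and 78, and DESeq2 613 and 682.

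Calls in ICM and TE overlapped. Of genes tested in both, 270 were higher in both against 46.5 expected from the numbers called, 316 lower in both against 70.1 expected, and 12 were called in opposite directions. With the length and GC trend removed, 365 were higher in both against 79.1 expected and 465 lower against 123. Between Epi and ExE, 20 were higher in both against 3.96 expected and 154 lower in both against 27.4. With the trend removed, when few genes were called in ExE, the numbers were 3 against 0.347 and 15 against 1.11.

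**Figure D5:**
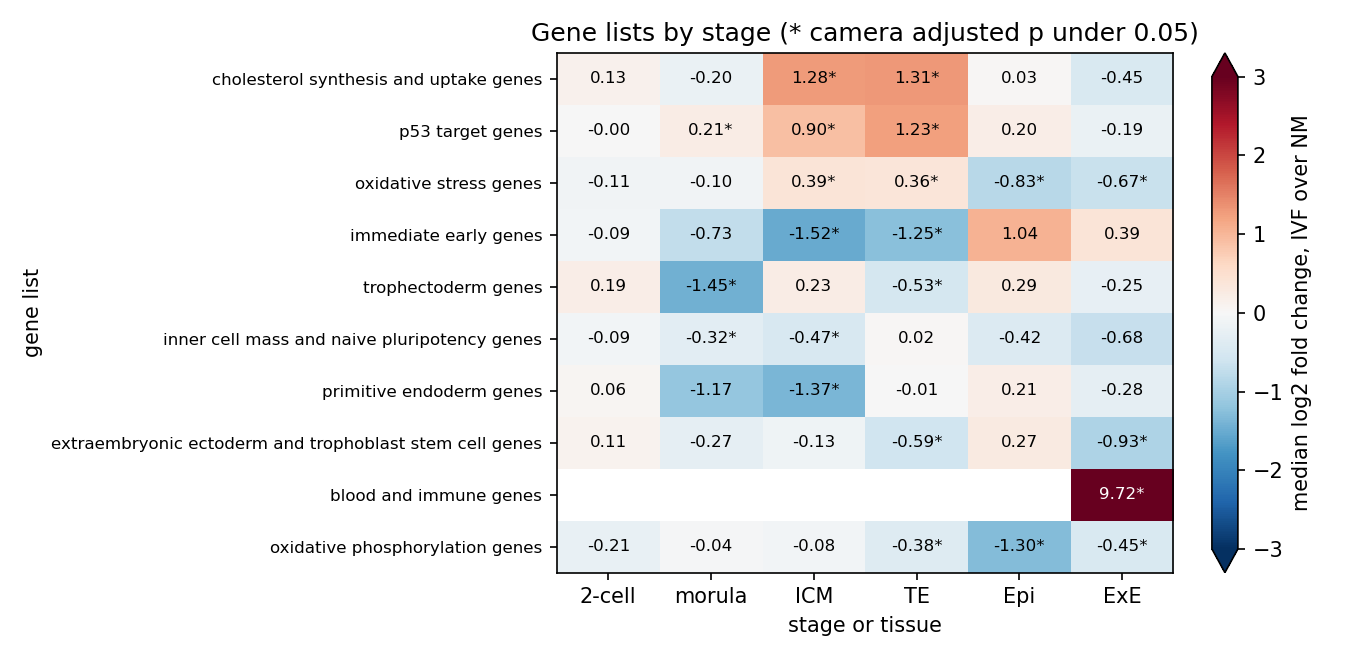
Each cell gives the median log2 fold change of a gene list with IVF, by list and by stage or tissue, with a star at a camera adjusted p under 0.05. The colour scale ends at -3 and 3, empty cells had fewer than 5 tested genes, and the 9.72 of blood genes becomes 6.55 with genes at 0 set to their bound.

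Lists without a call in any stage were the ectoplacental cone and later placenta genes (lowest adjusted p = 0.0583, in morulae), cumulus cell genes (0.162, in Epi, of 2 stages tested), oocyte maternal genes (0.201, at the 2-cell stage) and maternally expressed imprinted genes (0.281, in ExE). Positions in mm9 follow from the count table. Gata3 lies on chromosome 2 from 9778705 to 9800227, Klf5 on 14 from 99697910 to 99712628, Cyp51 on 5 from 4080674 to 4104697 and Sparc on 11 from 55207661 to 55233582. Hbb-bh1 lies on chromosome 7 from 110990152 to 110991676, Wnt7b on 15 from 85365867 to 85412251, Rps14 on 18 from 60934250 to 60938200 and Prtg on 9 from 72655081 to 72765114.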

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

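Tests chosen only after the result was seen are those of library preparation at E7.5, of ICM cells in TE and of blood cells in ExE, and the length and GC correction itself was added after seeing the data.

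The IVF effect differed between TE and ICM by a test of the difference itself, with 39 genes higher and 112 lower in TE. The differences (log2, TE minus ICM) were 3.42 for Gsc, 1.72 for Igf2bp1, 1.96 for Sap30, 2.1 for the amino acid response gene Asns and 4.13 for Cacnb1. They were -3.15 for Enpep, -4.97 for Enpp1, -2.41 for Perp, -3.09 for the immediate early gene Fos and -2.83 for Ank. Whether chance gives this count stays open. Of 100 splits of the libraries 8 gave as many genes as the real 151, the real one included, but each of the others kept or exchanged the labels of 1 tissue whole and so carried an IVF effect. The highest of them gave 3012, and it exchanged all 6 TE labels, so that the IVF effects of both tissues add up, which points to the effect they share.

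Between ExE and Epi, 164 genes differed upward and 57 downward in ExE by the same kind of test. The ribosomal protein genes Rps26, Rpl23a and Rpl10 differed by 2.21, 1.74 and 1.26, the mitochondrial ribosome gene Mrpl34 by 2.42 and Cox7b by 2.01. The length and GC trend was not removed in this test and was not separated from these differences. Ier3 and Cbl differed by -12.65 and -11.52, fitted values that depend on the prior count since both had 0 counts in NM Epi, and Elf1 by -7.92, and Igf2bp1 and Klhl22 by -1.91 and -4.42. As many genes as the real 221 came from 3 of 100 splits, the real one included. The other splits among these also kept or exchanged the labels of 1 tissue whole, the highest, with 2623, by exchanging all 6 Epi labels, so whether chance gives this count stays open as well.

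For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split gave 464 genes at the 2-cell stage, 698 in morulae, 1130 in ICM, 2411 in TE, 2567 in Epi, 275 in ExE, 2435 for TE against ICM and 528 for ExE against Epi in NM, each as 1 of 10 splits with a highest other of 0. Over all stages and tissues, 1 of 100 splits, the real one, reached 501 and the highest other gave 3, a share under 0.05. A chance division of these libraries thus seldom gives this count. The splits cannot exclude a day, pool or batch shared by the libraries of a group, since the labels do not say whether replicates were separate.

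Ribosomal protein genes were lower in Epi with IVF, which could be read as lower ribosome production. Their median log2 fold change of -2.28 became -0.45 with each library's trend on length and GC removed (interquartile range 0.943), and 41 of 90 were still called lower in place of 84. Most of the fall therefore went with length and GC. The correction removes a real fall that runs with length and GC as well as a technical one, so it cannot tell them apart. A library preparation that differed between NM and IVF at E7.5 cannot be told apart from the groups, because the share of even counts differed by 21.2 points with no overlap in Epi. A biological fall, of the whole or of the remaining size, stays open and was not tested.

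Trophectoderm genes such as Gata3, Elf5 and Gata2 were lower in TE with IVF. All 12 of the 12 that fell stayed lower with the length and GC trend removed (median -1.55 before and -1.6 after), which argues against that trend. Cells of the ICM in the IVF TE libraries would have to supply 75.2% of the RNA and raise the ICM genes by 1.3, but these changed by a median of 0.0634 (0.5 of their interquartile range is 0.555), with 4 of 16 called higher and 2 lower. That test first used the NM ICM profile and was changed to the measured IVF ICM profile after its result was seen, with the same outcome. It asked whether ICM cells give the whole median fall, so it does not exclude a smaller share of them. Delayed development, in which genes would lie closer to the morula, stays open.

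The test of delay asked whether the IVF effect in TE fell along the change from morula to ICM, across genes, which are not independent replicates. The Pearson r was -0.175 with NM libraries (-0.18 to -0.159 with 1 library left out) and 0.0165 with IVF libraries (0.00857 to 0.0233). By the bound set before the result, an r of 0 or more in either would have ruled delay out, and the IVF value met it. That bound was judged wrong, a decision made after the result. ICM shares the IVF effect of TE (r = 0.52 across genes), which can push the second r up with or without a delay. The shared effect can push the first r down if it lies in the NM libraries, which was not tested. A response of trophoblast genes to in vitro fertilization and culture is the biological reading that the design names, and it may act with or without delay.

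Globin genes were higher in ExE with IVF. Of 5 other blood genes tested, 4 were higher in every IVF than in every NM ExE library, which leaves blood or vessel cells from the embryo or the mother as a candidate source. With no filter, 10 of 19 other blood genes had a count in ExE, of which 4 were higher in every IVF library and 0 in every NM library. Hbb-bh1 still changed by 10.5 (SE 0.961) with the length and GC trend removed, which argues against that trend. Whether more blood reflects dissection, a later stage or a biological difference of IVF conceptuses was not tested.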

How the results depend on the processing

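The length and GC correction, halved counts and leaving out ribosomal protein genes were tests chosen only after the data were seen. Of named single genes, 1336 calls were kept with a library left out and 170 lost, and the fit of all 36 libraries kept 115 calls and ended 76. Calls were gained by 7 named genes with DESeq2, 5 in the fit of all 36 libraries, 2 with no low-count filter and 1 with a library left out. The cause of these changes, and of those below, was not tested. With an estimated correlation 33 list calls ended and 4 stayed, and with fry 4 ended and 33 stayed. With length and GC removed 27 gene and 10 list calls ended with their direction kept, and another 2 gene calls and 1 list call ended with a change of sign. Sign changed with length and GC removed for Mesp1 (0.41) and Utf1 (0.051) in Epi and the direction of the oxidative phosphorylation list in ExE turned up (camera adjusted p = 0.418), and without ICM of NM replicate 1 for Nanog (-0.024, with up to 0.432 without another library).

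Numbers of genes higher and lower moved past 1.5 times as follows. DESeq2 gave 737 and 785 at the 2-cell stage, 668 and 723 in morulae, 1048 and 1167 in ICM, 1983 higher in Epi, 721 and 850 in ExE, 855 and 841 for ExE against Epi in NM, 227 and 354 for TE minus ICM, 649 and 407 for ExE minus Epi, and 613 and 682 over all stages. No low-count filter gave 416 and 500 at the 2-cell stage, 504 higher in morulae, 683 higher in ICM, 120 and 385 in ExE, 484 and 410 for ExE against Epi, and 187 and 346 for TE minus ICM. The fit of all 36 libraries gave 121 higher at the 2-cell stage, 119 and 206 in morulae, 223 and 255 in ICM, 136 and 100 in TE, and 852 and 895 in ExE. A fold minimum of 2 gave 149 and 189 in morulae and 463 and 744 in TE, and a filter of 5 CPM gave 701 higher in Epi. Upper-quartile factors gave 100 and 129 in ExE.

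The replicate block gave 687 higher in Epi, 760 and 471 for TE against ICM in NM, 18 and 54 for TE minus ICM, and 28 and 78 over all stages. Length and GC removal gave 1043 lower in ICM, 597 lower in Epi, and 9 and 20 in ExE. Over all stages, 257 were higher without 2-cell, 63 and 218 without ICM, 66 and 222 without TE, 194 lower without Epi and 151 lower without ExE.

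With 1 library left out, higher and lower ranged from 27 to 488 and 6 to 477 at the 2-cell stage, 166 to 251 and 155 to 300 in morulae, 161 to 743 and 280 to 805 in ICM, 702 to 1219 and 821 to 1316 in TE, 170 to 1687 and 768 to 1529 in Epi, and 2 to 205 and 1 to 485 in ExE. They ranged from 795 to 1742 and 520 to 1274 for TE against ICM, 137 to 242 and 67 to 222 for ExE against Epi, 9 to 93 and 44 to 244 for TE minus ICM, and 52 to 258 and 9 to 97 for ExE minus Epi. The median of epiblast-high genes in ExE was 0.10 and 1.63 with a minimum of 1 and 4, 1.42 with length and GC removed (1.2 with the lists unchanged), and 0.75 to 1.40 with a library left out. That of ExE-high genes was -1.14 with a minimum of 4, -0.74 with length and GC removed (-0.75 with the lists unchanged), and -1.26 to -0.91 with a library left out.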

Other observations

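Tests chosen only after the result was seen are those of Y-linked genes and of the same genes in ICM and TE, and the test of the X chromosome was added after seeing the data with its bounds set before its value was known.

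In the blastocyst the genes changed with IVF in ICM and in TE overlapped. Calls in the same direction in both exceeded the number given by independent calls at least 4.51 times, with a Pearson r of 0.52 across genes, which are not independent replicates. Cholesterol synthesis genes such as Cyp51 and Fdps and the p53 targets Ccng1 and Phlda3 rose in both tissues, and Klf5, Plin3 and the immediate early genes Egr1 and Junb fell in both. A hypothesis is that culture changes sterol supply and stress signalling in the whole blastocyst, but day, batch or handling of IVF and NM blastocysts, whose share of Rn45s differed in both tissues, could give the same overlap, and no test here separates them. Overlaps with morula were smaller but also above the number expected. Morula and TE had 83 higher and 98 lower in both against 34.6 and 40.9 expected, and morula and ICM had 38 and 57 against 13.2 and 21.9.

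Magea genes, Xlr3a and Tceal8, all X-linked, were higher in ICM and TE with IVF. The median X-linked gene lay above the median autosomal gene by 0.298 in ICM and 0.327 in TE (camera p = 1.9e-04 and 2.4e-05, and 0.199 and 0.0501 with an estimated correlation), so higher expression of the X chromosome as a whole may add to these changes. The shift was not particular to the blastocyst: it was 0.343 in ExE (camera p = 0.00326, and 0.0242 with an estimated correlation), 0.205 at the 2-cell stage (0.0154 and 0.386), 0.137 in Epi and 0.0391 in morulae. More female embryos in the IVF libraries stay open: the 4 Y-linked genes had a median change of -0.313 in ICM and -1.28 in TE, but they moved apart, with Ddx3y at -1.83 in TE and Eif2s3y at 1.00 in ICM. Xist did not rise clearly, with 8.92 CPM in NM and 7.04 in IVF ICM and 11 and 14.5 in TE, and in ExE the 4 Y-linked genes were higher with IVF, which is opposite to more female embryos there. Reads shared between near-identical Magea copies leave the single genes uncertain.

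Levels of Emp2 were uneven between replicates. Its mean of 19100 CPM in NM ExE (SD 32900) rests on replicate 3 alone (57000), in which the 10 highest genes took 14.2% of counts, and IVF 2-cell libraries had 7750 ± 8290 (2020 to 17300). Gata3, the small chaperone Hspb8 and the heart and limb factor Hand2 had 0 counts in NM Epi and were at least 96.8-fold, 58.8-fold and 36-fold higher in IVF Epi. In ExE, Cdh5 and Alas2 had 0 counts in NM and were at least 93.9-fold and at least 45.4-fold higher, without passing the test (adjusted p = 0.0582 and 0.0841). DESeq2 (9.9e-06 and 0.00769) and the fit of all 36 libraries (0.0280 and 0.0429) called both, and Cdh5 was also called with no low-count filter (0.0366) and without NM replicate 1 (0.0492). These genes were chosen after their values were seen, and their bounds are lower if 2 counts stand for 1 fragment.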
